A study of Arabidopsis thaliana with 12 samples.

How the data were processed

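RNA sequencing was done on whole seedlings of Arabidopsis thaliana of 4 genotypes, with 3 replicates of each, 12 libraries in all. Per the labels, the plants were 7 days old, grew in short days at 21 °C and spent 12 h at 27 °C before RNA was taken. The genotype field gives the H3.3 line as h3.3kd-1 and the sample titles as h3.3kd, the name used here. Whether replicates with the same number were grown together, and whether they were separate cultures, is not given in the sources used here. The p-values therefore measure only the spread between these samples.

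The authors deposited 1 table of TPM (transcripts per 1000000) for 23387 genes, and each of its 12 columns sums to 1000000. Every deposited gene was above 0 in at least 1 library. Per the labels, the processing used fastp 0.20.1, HISAT2, HTSeq 0.11.2 and DESeq2 with genome build TAIR10, and the gene identifiers name the Araport11 annotation. The gene lengths behind the TPM values, the counting mode and any filter are not given in the sources used here. Raw reads and counts were not analysed here, so tests made for counts were not run. No 2 columns were identical, and 0 columns lacked a sample.

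Reads per library were estimated from the smallest steps between low TPM values, at 14.2 to 17.1 M reads. Of the values that this places under 20 reads, 26.1% to 28.8% came within 0.02 of a whole number, so the estimate is approximate. Symbols and products came from a reference annotation of build TAIR10.1, which matched 23235 identifiers and gave 9705 a symbol. It was used only for names and gene order.

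Values were taken as log2(TPM + 1) for the 19937 genes with a TPM of 1 or more in at least 3 of the 12 libraries. One limma 3.58.1 model held the 4 genotype means, with eBayes and an intensity trend. Each contrast was adjusted by Benjamini-Hochberg over all tested genes, and a gene was called at an adjusted p under 0.05. The contrasts were each mutant genotype against Col, the combined genotype against each of its parts, and the interaction. The interaction is the H3.3 effect in h2a.z plants minus the H3.3 effect in plants with H2A.Z. Software was R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

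The model, the comparisons, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined, except where a later choice is stated. In all, 19 gene lists with 308 genes were fixed, of which 304 were in the table. They were targeted histone genes, other H3 and H2A genes, histone variant machinery, thermomorphogenesis regulators, circadian clock, warmth-induced growth genes, heat shock response, flowering time, phosphate starvation, salicylic acid defence, jasmonate and ethylene defence, ABA with drought and cold, flavonoid and anthocyanin, photosynthesis, cell cycle, DNA damage response, root markers, seed and embryo markers, and floral organ and meristem markers. Each list was tested with limma camera at a preset correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation. Member calls were counted over all tested genes and adjusted over the list alone.

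Named genes were the 6 targeted histone genes, the 6 called genes with the largest change each way, and up to 3 called members of each list with the smallest adjusted p. Those of the largest change needed a symbol, a mean of at least 5 TPM in the higher genotype and libraries that did not overlap, which chance gives for 10% of genes with 3 libraries against 3. PIF4, YUC8, IAA19, IAA29 and HSP70-4 were always taken. For the interaction the 4 largest each way were taken without the overlap condition. Of the list members the rule took, those whose call ended when 1 library was left out were mostly kept out of the text, a choice made after the values were seen. They are counted with their lists.

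The method was tested on simulated data with the sizes and spread of this table. Changes were placed only in genes above a minimum mean level, so the shares recovered do not cover the lowest genes tested. In h3.3kd against Col it recovered 59% of 100 changes of 2-fold and 98% of 100 changes of 4-fold, with 5 unchanged genes called. For the interaction it recovered 21% and 87%, with 9 unchanged genes called. The 1 list that was moved was called, and none of the other lists was called (0 at an adjusted p under 0.05 by camera). Simulated genes varied independently of each other, so this does not cover lists whose members vary together.

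Alternatives were other pseudocounts (0.1 and 0.5), other filters, rescaling of each library by its median ratio, quantile normalization, the replicate number as a block, robust eBayes, array weights, only the genotypes compared, a 2-fold minimum and each library left out in turn. Leaving out Col 1 and h3.3kd 2 together was added after the data were seen, and so was a block for Col and h3.3kd alone. Of the same-numbered libraries, those of Col and h3.3kd deviated together from their genotype means in all 3 pairs (r = 0.31, 0.22 and 0.11). This pairing comes from the data and not from the labels. The block for Col and h3.3kd removes that shared spread, so calls gained with it are no independent check. Because both single comparisons share the 3 Col libraries, their overlap was set beside 50 simulations with no effect.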

Results

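Gene expression was measured by RNA sequencing in 12 seedling libraries, 3 from each of 4 genotypes held at 27 °C for 12 h. Col is the wild type. H3.3 and H2A.Z are histone variants that take the place of H3 and H2A in part of the nucleosomes. The names h3.3kd and h2a.z stand for plants with lowered H3.3 and without normal H2A.Z. The genotype h3.3kd;h2a.z, here the combined line, carries both changes. No library came from plants left at 21 °C, so the response to warmth itself was not measured. Estimated depth ran from 14.2 M reads (Col 2) to 17.1 M (h2a.z 3). Between 19590 (h3.3kd 2) and 22019 (h2a.z 3) genes were above 0. Means are TPM ± SD with n = 3 libraries per genotype, and log2 fold changes are given ± standard error.

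The genes that encode each variant were low in the lines named after it. Of the H3.3 genes, HTR4 (AT4G40030) stood at 448 ± 30.9 TPM in Col and 55.1 ± 22.2 in h3.3kd (n = 3, log2 fold change -3.09 ± 0.24, adjusted p = 3.7e-06). HTR5 (AT4G40040) stood at 478 ± 61.1 and 79.4 ± 16.2 (-2.59 ± 0.17, adjusted p = 1.4e-06), and HTR8 (AT5G10980) at 239.8 ± 50.7 and 11.1 ± 1.56 (-4.31 ± 0.16, adjusted p = 1.5e-09). In the combined line they were as low, at 54.7 ± 6.45, 63.7 ± 12.3 and 8.55 ± 0.431 TPM. Of the H2A.Z genes, HTA8 (AT2G38810) fell from 14.8 ± 2.34 TPM in Col to 0.0202 ± 0.0349 in h2a.z (-3.94 ± 0.22, adjusted p = 3.4e-08). HTA11 (AT3G54560) fell from 46.3 ± 16.2 to 2.58 ± 0.869 (-3.70 ± 0.26, adjusted p = 3.2e-07). HTA9 (AT1G52740) fell from 255 ± 61.3 to 32.1 ± 2.08 TPM in h2a.z (-2.93 ± 0.22, adjusted p = 5.2e-07), and stood higher again in the combined line, at 87.2 ± 8.79 TPM (1.41 ± 0.22, adjusted p = 3.1e-04, against h2a.z).

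As a list the 6 targeted genes had 4 lower in h3.3kd than in Col (adjusted p = 2.2e-05, and adjusted p = 0.20 with an estimated correlation). In h2a.z 5 were lower (adjusted p = 3.7e-08, and adjusted p = 0.071 with an estimated correlation) and in the combined line 6 (adjusted p = 1.7e-11, and adjusted p = 0.025 with an estimated correlation). The same numbers were lower adjusted over the list alone. The fourth in h3.3kd was HTA8 (-0.70 ± 0.22, adjusted p = 0.04), a call that ended under several settings (0.009 to 0.24). Leaving out any library but h3.3kd 1 ended it, at 0.15 without Col 1, 0.06 without Col 2, 0.066 without Col 3, 0.082 without h3.3kd 2, 0.092 without h3.3kd 3, 0.052 without h2a.z 1, 0.057 without h2a.z 2, 0.056 without h2a.z 3, 0.056 without h3.3kd;h2a.z 1, 0.054 without h3.3kd;h2a.z 2 and 0.054 without h3.3kd;h2a.z 3. In h2a.z, HTR5 was lower as well (-0.65 ± 0.17, adjusted p = 0.014), a call that ended at 0.056 without Col 1, 0.051 without h2a.z 1 and 0.062 without h2a.z 2, with 0.0036 to 0.062 over all settings. So was HTR8 (-0.49 ± 0.16, adjusted p = 0.045), with 0.0088 to 0.18 over all settings. Its call ended at 0.18 without Col 1, 0.075 without Col 3, 0.054 without h3.3kd 3, 0.12 without h2a.z 1, 0.18 without h2a.z 2, 0.079 without h2a.z 3, 0.065 without h3.3kd;h2a.z 1, 0.062 without h3.3kd;h2a.z 2 and 0.062 without h3.3kd;h2a.z 3.

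**Figure D1:**
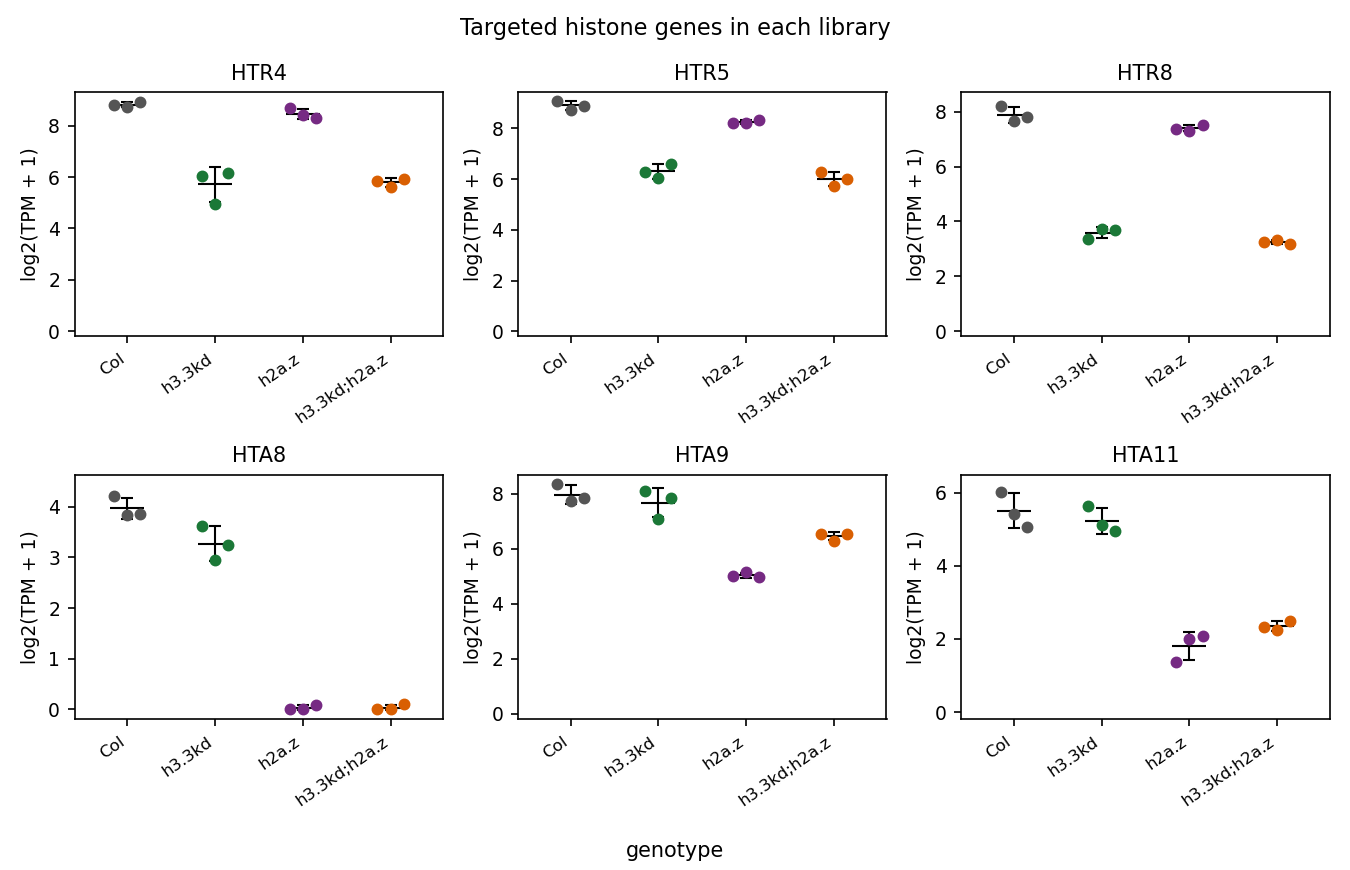
Transcript level of the 6 targeted histone genes as log2(TPM + 1), 1 point per library with the mean and SD of 3 libraries per genotype. The H3.3 genes HTR4, HTR5 and HTR8 sit low in h3.3kd and the combined line, and HTA8 and HTA11 in h2a.z and the combined line, while HTA9 has a mean of 32.1 TPM in h2a.z and 87.2 TPM in the combined line.

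Libraries of a genotype were close to each other, with mean correlations across genes of 0.964 (h3.3kd) to 0.986 (the combined line). Between genotypes the combined line was nearest to h3.3kd (mean r 0.961 over 9 pairs), and h3.3kd and h2a.z were farthest apart (0.903). Genes are not independent replicates, so no test goes with these values. The library h3.3kd 2 lay farthest from its genotype mean (root mean square 0.405 on the log2 scale), followed by h3.3kd 1 (0.324) and Col 1 (0.314). It had 0.587% of its TPM in chloroplast genes, against 0.171% to 0.347% in the other libraries. The 10 most abundant genes held 9.66% of the TPM in h3.3kd and 10.2% in the combined line, against 7.64% in Col and 6.64% in h2a.z.

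**Figure D2:**
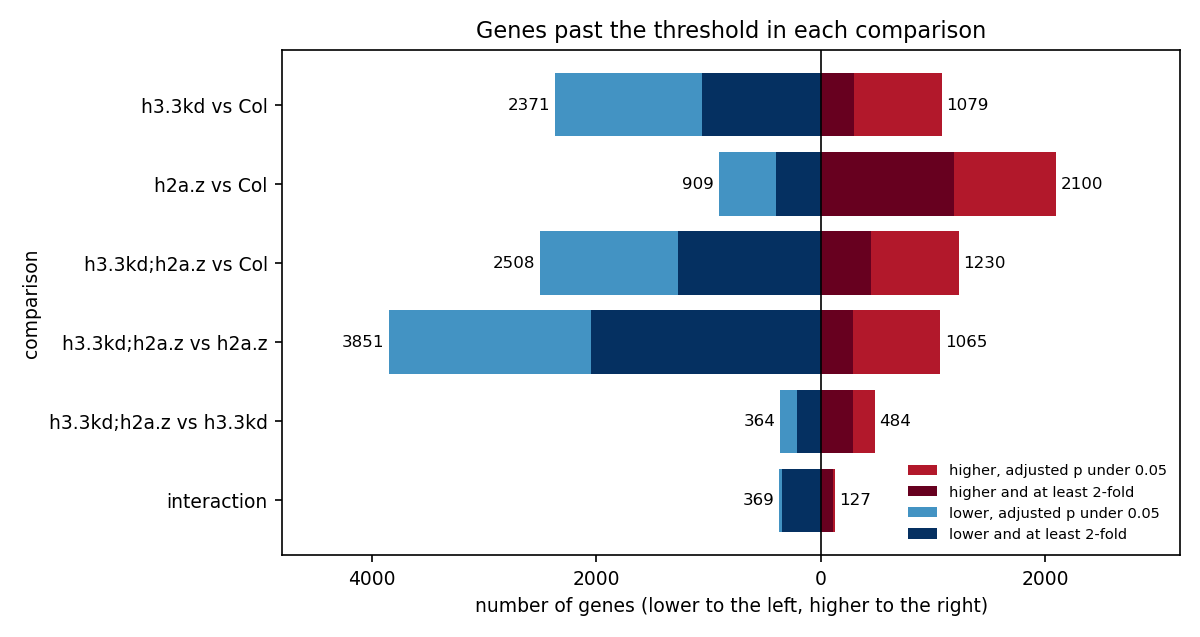
Number of genes called lower or higher (limma, adjusted p under 0.05, 19937 genes tested) in each comparison, with genes changed at least 2-fold in the dark part of each bar. Calls are mostly lower in h3.3kd (2371 of 3450) and in the combined line (2508 of 3738) and mostly higher in h2a.z (2100 of 3009), each against Col.

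The comparison of h3.3kd with Col asks what lowered H3.3 changes in warm-grown seedlings. CRC (AT4G28520), which encodes a cruciferin seed storage protein, rose from 0.0321 ± 0.0556 to 23.7 ± 8.86 TPM (n = 3, log2 fold change 4.52 ± 0.43, adjusted p = 1.6e-05). CRA1 (AT5G44120), another cruciferin, rose from 0.525 ± 0.525 to 24.4 ± 12.5 (adjusted p = 1.1e-04). HIS1-3 (AT2G18050), a linker histone known from drought-stressed plants, rose from 90.7 ± 35.7 to 1342 ± 332 TPM (3.93 ± 0.28, adjusted p = 2.0e-06). CYP83A1 (AT4G13770), a cytochrome P450 of aliphatic glucosinolate synthesis, fell from 26.5 ± 9.35 to 0.622 ± 0.0375 TPM (-4.02 ± 0.29, adjusted p = 2.5e-06).

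Further seed proteins were among the largest rises, the storage albumin SESA5 (AT5G54740) (4.16 ± 0.90, adjusted p = 0.0065), ECP63 (AT2G36640) (3.49 ± 0.48, adjusted p = 3.3e-04) and PAP85 (AT3G22640) (2.97 ± 0.48, adjusted p = 0.0011). SESA5 was uneven, at 1.97 TPM in h3.3kd 1 against 44.9 and 51.4 in the other libraries of that genotype. Among the largest falls were PRP2 (AT2G21140), a proline-rich cell wall protein (-3.22 ± 0.30, adjusted p = 1.6e-05), AZI1 (AT4G12470), a lipid transfer protein of systemic immunity (-3.19 ± 0.56, adjusted p = 0.0018), and IPMI2 (AT2G43100), an isomerase of methionine chain elongation (-2.95 ± 0.37, adjusted p = 1.4e-04).

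Of the 23 warmth-induced growth genes tested, 9 fell and 0 rose (11 and 0 adjusted over the list alone), with a median of -0.56 (adjusted p = 1.7e-04, and adjusted p = 0.29 with an estimated correlation). XTR7 (AT4G14130), a xyloglucan-modifying wall enzyme, fell from 68.1 ± 7.71 to 16.9 ± 3.16 TPM (-1.96 ± 0.18, adjusted p = 1.1e-05). ACS8 (AT4G37770), of ethylene synthesis, fell from 15.2 ± 4.15 to 2.17 ± 0.854 (-2.36 ± 0.28, adjusted p = 1.1e-04) and IAA29 (AT4G32280), an auxin response gene, from 68.0 ± 32.8 to 19.4 ± 6.90 (-1.72 ± 0.29, adjusted p = 0.0012). IAA19 (AT3G15540), another auxin response gene, was also lower (-1.79 ± 0.38, adjusted p = 0.0056), though at 0.061 in a model of h3.3kd and Col alone, with 3.3e-04 to 0.061 over all settings. YUC8 (AT4G28720), an auxin synthesis enzyme, was lower too (-0.83 ± 0.21, adjusted p = 0.017), a call that ended at 0.056 without Col 1, 0.056 without Col 2 and 0.053 without h3.3kd 3, with 0.0082 to 0.056 over all settings. PIF4 (AT2G43010), the transcription factor at the centre of warmth responses, stood at 36.9 ± 7.60 TPM in Col and 36.6 ± 4.34 in h3.3kd (adjusted p = 1).

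Genes of ABA, drought and cold went the other way, with 8 of 17 higher and 2 lower (12 and 2 adjusted over the list alone). The list test gave adjusted p = 2.0e-06, and adjusted p = 0.29 with an estimated correlation. RD29B (AT5G52300) rose from 47.3 ± 3.63 to 179 ± 20.4 TPM (1.90 ± 0.21, adjusted p = 5.6e-05). RD29A (AT5G52310) rose from 16.6 ± 2.15 to 70.5 ± 34.0 (1.91 ± 0.27, adjusted p = 3.9e-04) and P5CS1 (AT2G39800), which makes proline, from 38.1 ± 9.60 to 90.3 ± 10.2 (1.24 ± 0.17, adjusted p = 2.5e-04). Seed and embryo markers had 4 of 7 higher and 0 lower, the same adjusted over the list alone (adjusted p = 3.7e-05, and adjusted p = 0.041 with an estimated correlation). Among them was the oleosin OLEO1 (AT4G25140) (1.65 ± 0.34, adjusted p = 0.0047). Root markers had 5 of 16 lower and 0 higher (10 and 0 adjusted over the list alone). As a list they had adjusted p = 0.0051, and adjusted p = 0.74 with an estimated correlation. Their fold changes ran from -1.53 for IRT1 (AT4G19690), the root iron transporter, to 0.23 for SCR.

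The other 14 lists did not pass the list test (adjusted p 0.086 to 0.97), though some members changed. Heat shock genes moved both ways, with 3 higher and 3 lower of 29 (3 and 6 adjusted over the list alone). The small heat shock protein HSP23.5 (AT5G51440) rose (1.11 ± 0.22, adjusted p = 0.0041) and the chaperone partner ROF1 (AT3G25230) fell (-0.72 ± 0.17, adjusted p = 0.0092). HSP70-4 (AT3G12580), a heat-induced chaperone, did not pass (-0.16 ± 0.14, adjusted p = 0.46). Of the phosphate starvation genes, 3 rose and 4 fell of 14, as many adjusted over the list alone. The latter included the non-coding AT4 (AT5G03545) (-2.84 ± 0.37, adjusted p = 2.0e-04) and the transporter PHT1;4 (AT2G38940) (-1.55 ± 0.26, adjusted p = 0.0013). The flowering activator SOC1 (AT2G45660) rose from 2.22 ± 0.350 to 6.86 ± 0.948 TPM (1.29 ± 0.22, adjusted p = 0.0015). The replication clamp PCNA1 (AT1G07370) fell from 24.2 ± 5.71 to 10.2 ± 2.06 (-1.16 ± 0.19, adjusted p = 0.0013), and the Rubisco gene RBCS1B (AT5G38430) from 872 ± 84.8 to 519 ± 71.5 (-0.75 ± 0.13, adjusted p = 0.0018). PR5 (AT1G75040), a pathogenesis-related protein, was at 3.73 ± 0.344 TPM in Col and listed at 0 in every h3.3kd library.

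Of 19937 genes, 1079 were higher and 2371 lower in h3.3kd, 31.3% higher, with a median log2 fold change over all genes of -0.12. Leaving out h3.3kd 3 gave 711 higher, leaving out Col 1 gave 1427 lower, and leaving out h3.3kd 1 gave 40.2% higher. With the replicate number as a block for Col and h3.3kd, 1680 were higher and 3357 lower, and a model of these 2 genotypes alone gave 287 and 784. Rescaled by median ratios, which moved the median of all genes to -0.02, 1733 were higher and 1876 lower (48.0% higher). Quantile normalization gave 52.8% higher and a median of 0.02. List test and median or mean differed in sign for 9 lists, none of which passed. These were other H3 and H2A genes, thermomorphogenesis regulators, clock, heat shock, flowering, both defence lists, photosynthesis and DNA damage response.

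**Figure D3:**
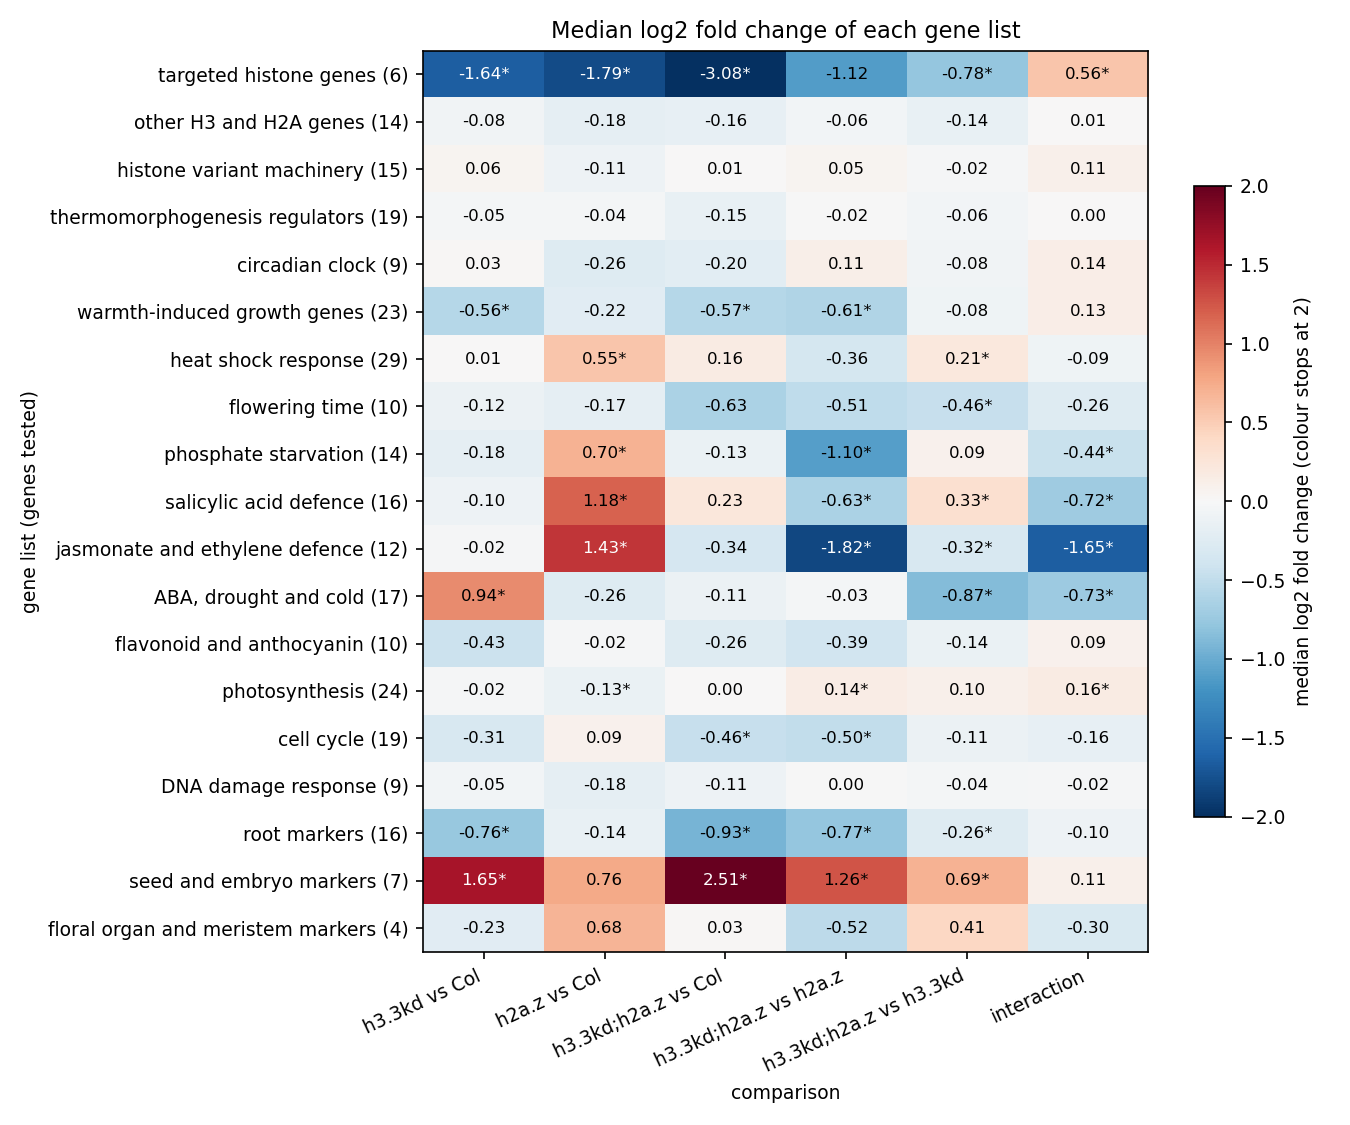
Median log2 fold change of each fixed gene list (genes tested in parentheses) in the 6 contrasts, with an asterisk where limma camera gave an adjusted p under 0.05 at the preset correlation. Seed and embryo markers have medians of 1.65 in h3.3kd and 2.51 in the combined line against Col, and jasmonate and ethylene defence has 1.43 in h2a.z against Col and -1.82 in the combined line against h2a.z.

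What changes without normal H2A.Z was asked by comparing h2a.z with Col. Several defence genes were higher, and a set of single transcripts was nearly gone. PDF1.2A (AT5G44420), a defensin used as a marker of jasmonate and ethylene signalling, was listed at 0 in every Col library and stood at 17.9 ± 4.66 TPM in h2a.z (n = 3, adjusted p = 2.9e-08). ORA59 (AT1G06160), a transcription factor of that pathway, rose from 0.828 ± 0.746 to 12.3 ± 0.606 TPM (log2 fold change 2.95 ± 0.34, adjusted p = 4.1e-05). WRKY70 (AT3G56400), a regulator of salicylic acid responses, rose from 2.61 ± 0.881 to 13.4 ± 1.38 (2.02 ± 0.27, adjusted p = 1.4e-04). ESM1 (AT3G14210), a modifier of glucosinolate breakdown, fell from 228 ± 35.4 to 14.7 ± 2.01 TPM (-3.87 ± 0.16, adjusted p = 2.1e-09).

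Of 12 jasmonate and ethylene defence genes, 7 rose and 0 fell (8 and 0 adjusted over the list alone). For this list camera gave adjusted p = 2.7e-06, and adjusted p = 0.071 with an estimated correlation. The repressor JAZ1 (AT1G19180) went from 8.81 ± 1.35 to 38.7 ± 5.94 TPM (2.02 ± 0.26, adjusted p = 9.2e-05). Of 16 salicylic acid defence genes, 11 rose and 1 fell, as many adjusted over the list alone (adjusted p = 1.1e-05, and adjusted p = 0.10 with an estimated correlation). PR5 rose from 3.73 ± 0.344 to 21.3 ± 5.58 TPM (2.21 ± 0.26, adjusted p = 4.5e-05). The receptor gene SNC1 (AT4G16890) fell from 72.1 ± 14.0 to 22.9 ± 3.40 (-1.60 ± 0.26, adjusted p = 6.7e-04). Phosphate starvation genes had 5 of 14 higher and 0 lower (9 and 0 adjusted over the list alone). List-wide, camera gave adjusted p = 3.3e-04, and adjusted p = 0.14 with an estimated correlation. GDPD1 (AT3G02040) (1.46 ± 0.20, adjusted p = 1.7e-04) and PLDZ2 (AT3G05630) (1.21 ± 0.21, adjusted p = 0.001), enzymes that break down membrane lipids, rose.

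Heat shock genes had 11 of 29 higher and 1 lower (13 and 1 adjusted over the list alone). Taken as a list, these had adjusted p = 0.0013, and adjusted p = 0.18 with an estimated correlation. HSP70-4 rose from 45.5 ± 3.61 to 88.1 ± 15.2 TPM (0.92 ± 0.14, adjusted p = 3.2e-04) and HSP23.5 from 8.94 ± 2.42 to 27.0 ± 5.56 (adjusted p = 3.1e-04). DREB2A (AT5G05410), a transcription factor upstream of heat genes, fell from 18.5 ± 0.594 to 7.52 ± 0.104 (-1.19 ± 0.17, adjusted p = 2.2e-04). Photosynthesis genes were lower as a list (adjusted p = 0.0057, and adjusted p = 0.58 with an estimated correlation). Of 24, 2 were called lower and 0 higher (1 and 0 adjusted over the list alone), among them the antenna protein LHCB4.2 (AT3G08940) (-1.29 ± 0.22, adjusted p = 0.0011).

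The growth genes did not pass as a list (adjusted p = 0.34), with 5 higher and 2 lower of 23, as many adjusted over the list alone. CYP79B2 (AT4G39950) (1.39 ± 0.28, adjusted p = 0.0038) and TAA1 (AT1G70560) (0.80 ± 0.18, adjusted p = 0.0078), enzymes on routes to auxin, rose. IAA29 was at 29.1 ± 1.28 TPM (-1.10 ± 0.29, adjusted p = 0.017), a call that ended at 0.067 without Col 1, 0.055 without h2a.z 1 and 0.061 without h2a.z 2, with 1.5e-04 to 0.067 over all settings. PIF4 was at 21.1 ± 7.33 TPM (-0.81 ± 0.21, adjusted p = 0.016), ending at 0.079 without Col 3, 0.081 without h2a.z 2 and 0.09 without h2a.z 3, with 2.7e-04 to 0.09 over all settings. YUC8 (-0.32 ± 0.21, adjusted p = 0.37) and IAA19 (-0.63 ± 0.38, adjusted p = 0.32) did not pass. FLC (AT5G10140), the flowering repressor, fell from 12.6 ± 2.01 to 4.91 ± 0.921 TPM (-1.20 ± 0.19, adjusted p = 5.7e-04). RD29B fell from 47.3 ± 3.63 to 20.4 ± 8.15 (-1.23 ± 0.21, adjusted p = 8.5e-04). The seed list did not pass (0.097), with 3 higher and 1 lower of 7, the same adjusted over the list alone. The seed regulator ABI3 (AT3G24650) fell from 2.98 ± 0.0627 to 0.358 ± 0.353 (-1.58 ± 0.30, adjusted p = 0.0024).

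Among the largest changes upward were CRA1, at 77.7 TPM (5.50 ± 0.48, adjusted p = 2.5e-06), and CRC, at 37.5 ± 19.3 (5.06 ± 0.43, adjusted p = 1.9e-06). EARLI1 (AT4G12480), a lipid transfer protein, stood at 201 ± 87.8 TPM against 0.982 ± 0.319 in Col (6.60 ± 0.55, adjusted p = 1.8e-06). DIN11 (AT3G49620), a dioxygenase (4.65 ± 0.32, adjusted p = 2.5e-07), was also higher. NATA1 (AT2G39030), an acetyltransferase induced by jasmonate, was listed at 0 in Col and stood at 33.8 ± 26.3 TPM in h2a.z. Among genes with a symbol, the largest falls besides ESM1 and the H2A.Z genes were those of JAL33 and SEH. JAL33 (AT3G16450), a lectin, fell from 157 ± 10.9 to 8.05 ± 2.42 TPM (-4.15 ± 0.22, adjusted p = 2.9e-08). SEH (AT2G26740) is an epoxide hydrolase (-3.42 ± 0.23, adjusted p = 2.1e-07). LEA18 (AT2G35300), a late embryogenesis protein, fell too (-3.42 ± 0.39, adjusted p = 3.5e-05).

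Besides the targeted histone genes, 34 annotated transcripts with at least 5 TPM in Col were more than 16-fold lower in h2a.z. There were 11 in h3.3kd and 38 in the combined line, and h2a.z and the combined line shared 9. Of the 34, 19 were within 4-fold of Col in the combined line and 15 were not. Genes of the set within 10 places of each other were counted once, by the first. Successive members on a chromosome, more than 10 places apart, were both within 4-fold, or both not, in 18 of 24 pairs. The set includes RPP5 (AT4G16950), a TIR-NBS-LRR resistance gene (27.8 TPM in Col, 1.72 ± 0.194 in h2a.z, 42.7 ± 3.06 in the combined line). Also in it are PAI3 (AT1G29410), listed at 0 in h2a.z and at 6.26 ± 1.13 in the combined line, and JAL33, at 1.42 ± 0.414 in the combined line. SNC1 lies beside RPP5 in the same resistance gene cluster on chromosome 4.

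**Figure D4:**
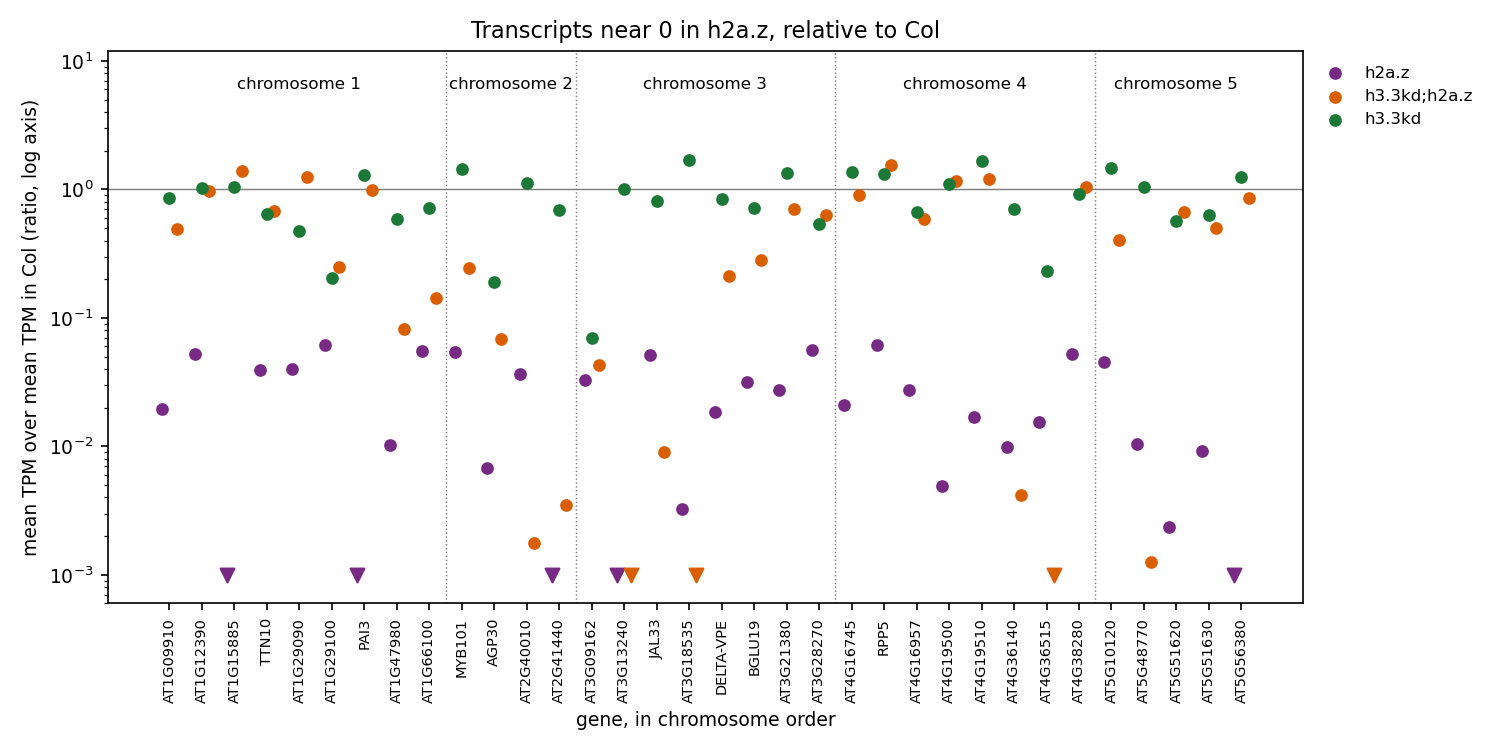
Mean TPM of 34 transcripts as a ratio to Col on a log axis, in chromosome order, with points for h3.3kd, h2a.z and the combined line and triangles for ratios under 0.001. In the combined line 19 of the transcripts are within 4-fold of Col and 15 are not.

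In h2a.z 2100 genes were higher and 909 lower (69.8% higher). Quantile normalization gave 1896 higher and 1578 lower (54.6% higher). Leaving out h2a.z 2 gave 1254 higher and 514 lower, and leaving out h2a.z 3 gave 1252 and 590. The other 13 lists did not pass (adjusted p 0.097 to 0.77), the histone variant machinery with a test and median below 0 and a mean above it (-0.11 and 0.01).

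The combined line against Col asks what both changes do together. CRA1 rose from 0.525 ± 0.525 to 159 ± 68.5 TPM (n = 3, log2 fold change 6.68 ± 0.48, adjusted p = 4.6e-07) and CRC from 0.0321 ± 0.0556 to 90.6 ± 54.7 (6.32 ± 0.43, adjusted p = 2.8e-07). XTR7 fell from 68.1 ± 7.71 to 15.6 ± 3.07 TPM (-2.07 ± 0.18, adjusted p = 2.9e-06), IAA29 to 13.3 ± 1.16 (-2.17 ± 0.29, adjusted p = 1.2e-04) and PIF4 to 18.8 ± 0.873 (-0.92 ± 0.21, adjusted p = 0.0067). FLC fell to 2.21 ± 0.237 TPM (-2.07 ± 0.19, adjusted p = 6.4e-06) and SOC1 rose to 9.60 ± 1.21 (1.72 ± 0.22, adjusted p = 1.0e-04).

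Of 23 growth genes, 10 fell and 1 rose, as many adjusted over the list alone (adjusted p = 0.0021, and adjusted p = 0.52 with an estimated correlation). The lower genes included YUC8 (-1.02 ± 0.21, adjusted p = 0.0042), IAA19 (-2.25 ± 0.38, adjusted p = 8.9e-04) and ACS8 (-2.85 ± 0.28, adjusted p = 1.1e-05). Root markers had 10 of 16 lower and 0 higher (14 and 1 adjusted over the list alone). Camera gave the list adjusted p = 1.1e-04, and adjusted p = 0.55 with an estimated correlation. IRT1 fell to 5.19 ± 1.96 TPM (-2.29 ± 0.32, adjusted p = 2.2e-04). The root hair expansins EXPA7 (AT1G12560) (-1.81 ± 0.28, adjusted p = 5.3e-04) and EXPA18 (AT1G62980) (-1.74 ± 0.26, adjusted p = 4.1e-04) fell with it. Cell cycle genes had 5 of 19 lower and 0 higher (8 and 0 adjusted over the list alone). The list test gave adjusted p = 0.0082, and adjusted p = 0.60 with an estimated correlation. AUR1 (AT4G32830), a mitotic kinase, fell (-0.90 ± 0.19, adjusted p = 0.0039), as did PCNA1 (-0.90 ± 0.19, adjusted p = 0.0049). Seed and embryo markers had 5 of 7 higher and 0 lower, the same adjusted over the list alone (adjusted p = 1.9e-06, and adjusted p = 0.018 with an estimated correlation).

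Among genes with a symbol, large rises besides the cruciferins were PAP85 (5.70 ± 0.48, adjusted p = 2.9e-06), SESA5 (5.48 ± 0.90, adjusted p = 7.4e-04), and SESA2 (AT4G27150) (3.82 ± 0.69, adjusted p = 0.0015). The transporter ABCA9 (AT5G61730) rose from 0.0160 ± 0.0277 to 15.8 ± 2.40 TPM (4.04 ± 0.19, adjusted p = 1.1e-08) and stood at 15.1 ± 0.928 in h2a.z. The largest falls among genes with a symbol were ESM1, to 0.637 ± 0.173 TPM (-7.12 ± 0.16, adjusted p = 1.5e-12), JAL33 (-6.04 ± 0.22, adjusted p = 5.8e-10), SEH (-4.86 ± 0.23, adjusted p = 1.1e-08) and HTR8. Of the genes with a symbol, they were followed by CYP83A1 (-4.46 ± 0.29, adjusted p = 2.3e-07) and the glutathione transferase GSTU8 (AT3G09270) (-4.45 ± 0.27, adjusted p = 1.5e-07). Of the heat shock genes 4 rose and 2 fell, as many adjusted over the list alone, HSP23.5 among the former (1.35 ± 0.22, adjusted p = 7.4e-04), and HSP70-4 did not pass (0.16 ± 0.14, adjusted p = 0.45). The dehydrins LTI30 (AT3G50970) (-2.33 ± 0.17, adjusted p = 8.2e-07) and COR47 (AT1G20440) (-1.12 ± 0.17, adjusted p = 5.0e-04) fell, as did LDOX (AT4G22880) (-1.44 ± 0.30, adjusted p = 0.0043), an enzyme of anthocyanin synthesis. LHCB1.2 (AT1G29910), an antenna protein, rose (1.14 ± 0.27, adjusted p = 0.0095).

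In the combined line 1230 genes were higher and 2508 lower than in Col (32.9% higher), with 45.9% higher after median-ratio rescaling and 50.2% after quantile normalization. With the block for Col and h3.3kd 1861 were higher. Leaving out 1 library of the combined line gave 777, 757 or 761 higher (replicates 1, 2 and 3). Leaving out Col 1, combined 2 or combined 3 gave 1651, 1599 or 1654 lower. The other 14 lists did not pass (adjusted p 0.094 to 0.92), and for photosynthesis and DNA damage response the test was above 0 with a mean or median below it.

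The combined line against h2a.z asks how lowered H3.3 changes plants that already lack normal H2A.Z. PDF1.2A was at 17.9 ± 4.66 TPM in h2a.z and listed at 0 in every combined library (n = 3, adjusted p = 3.9e-08). ORA59 fell from 12.3 ± 0.606 to 0.332 ± 0.384 TPM (log2 fold change -3.36 ± 0.34, adjusted p = 1.1e-05) and the jasmonate synthesis gene AOC1 (AT3G25760) from 26.3 ± 8.58 to 3.49 ± 0.624 (-2.56 ± 0.27, adjusted p = 1.4e-05). WRKY70 fell from 13.4 ± 1.38 to 2.87 TPM (-1.95 ± 0.27, adjusted p = 1.4e-04) and PR5 from 21.3 ± 5.58 to 0.299 ± 0.445 (-4.12 ± 0.26, adjusted p = 1.9e-07). HIS1-3 rose from 26.1 ± 6.53 to 698 ± 66.9 TPM (4.72 ± 0.28, adjusted p = 9.7e-08).

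Jasmonate and ethylene defence genes had 10 of 12 lower and 0 higher (11 and 0 adjusted over the list alone). As a list they had adjusted p = 1.2e-06, and adjusted p = 0.054 with an estimated correlation. Salicylic acid defence had 8 of 16 lower and 1 higher, as many adjusted over the list alone (adjusted p = 0.013, and adjusted p = 0.44 with an estimated correlation). The higher gene was SNC1 (1.97 ± 0.26, adjusted p = 9.0e-05). Phosphate starvation had 9 of 14 lower and 0 higher, the same adjusted over the list alone (adjusted p = 0.0024, and adjusted p = 0.30 with an estimated correlation). AT4 (-3.22 ± 0.37, adjusted p = 2.7e-05), PHT1;4 (-2.05 ± 0.26, adjusted p = 6.8e-05) and the lipid synthase MGD2 (AT5G20410) (-1.46 ± 0.23, adjusted p = 3.7e-04) fell. Growth genes had 11 of 23 lower and 0 higher (13 and 0 adjusted over the list alone). For this list camera gave adjusted p = 0.013, and adjusted p = 0.44 with an estimated correlation. XTR7 (-2.05 ± 0.18, adjusted p = 2.5e-06), IAA29 (-1.08 ± 0.29, adjusted p = 0.013) and IAA19 (-1.62 ± 0.38, adjusted p = 0.006) fell, while PIF4 did not pass (-0.11 ± 0.21, adjusted p = 0.75). YUC8 (-0.70 ± 0.21, adjusted p = 0.027) lost its call at 0.067 without h2a.z 2, 0.13 without h2a.z 3 and 0.15 without h3.3kd;h2a.z 1. It also lost it at 0.083 after median-ratio rescaling and at 0.12 after quantile normalization, with 0.0028 to 0.15 over all settings.

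Cell cycle genes had 9 of 19 lower and 0 higher (10 and 0 adjusted over the list alone). List-wide, camera gave adjusted p = 0.011, and adjusted p = 0.44 with an estimated correlation. MCM2 (AT1G44900) (-0.97 ± 0.19, adjusted p = 0.0022) and PCNA1 (-1.19 ± 0.19, adjusted p = 4.8e-04), of DNA replication, fell. Root markers had 8 of 16 lower and 0 higher (11 and 0 adjusted over the list alone). Taken as a list, these had adjusted p = 0.0024, and adjusted p = 0.44 with an estimated correlation. IRT1 fell from 64.5 ± 8.65 to 5.19 ± 1.96 TPM (-3.44 ± 0.32, adjusted p = 5.2e-06), and the root hair regulator RHD6 (AT1G66470) fell as well (-1.58 ± 0.31, adjusted p = 0.0018). Seed and embryo markers had 5 of 7 higher and 0 lower (6 and 0 adjusted over the list alone). Camera gave the list adjusted p = 2.8e-04, and adjusted p = 0.054 with an estimated correlation. The albumin SESA1 (AT4G27140) rose (1.96 ± 0.46, adjusted p = 0.0063). Photosynthesis genes were higher as a list (adjusted p = 0.0032, and adjusted p = 0.44 with an estimated correlation). Of 24, 3 were called higher and 3 lower, as many adjusted over the list alone. LHCB1.2 rose (1.82 ± 0.27, adjusted p = 2.6e-04) and LHCB2.2 (AT2G05070) fell (adjusted p = 8.2e-04, 77.1 ± 8.80 to 30.8 ± 4.52 TPM). HSP70-4 fell from 88.1 ± 15.2 to 51.1 ± 1.72 TPM (-0.76 ± 0.14, adjusted p = 0.0011). The heat shock list did not pass (adjusted p = 0.24), with 10 lower and 1 higher (11 and 1 adjusted over the list alone).

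Upward, PGAZAT (AT2G41850), a pectin-degrading enzyme, went from 2.30 ± 0.910 to 81.0 ± 19.4 TPM (4.64 ± 0.30, adjusted p = 2.0e-07) and RPP5 from 1.72 ± 0.194 to 42.7 ± 3.06 (4.01 ± 0.22, adjusted p = 4.3e-08). PAI3 and GH9B15 (AT4G23560), a wall hydrolase, were listed at 0 in h2a.z and stood at 6.26 ± 1.13 and 9.66 ± 5.57 TPM. MRD1 (AT1G53480), listed at 0 in h2a.z and in Col, stood at 5.74 ± 0.205. Downward, CYP83A1 went from 42.9 ± 13.4 to 0.221 ± 0.331 TPM (-5.15 ± 0.29, adjusted p = 7.9e-08). BCAT4 (AT3G19710), which starts methionine chain elongation, fell from 35.2 ± 12.9 to 0.721 ± 0.455 (-4.35 ± 0.31, adjusted p = 4.4e-07) and the methylesterase MES18 (AT5G58310) from 58.1 ± 11.8 to 0.955 ± 0.734 (-4.97 ± 0.26, adjusted p = 3.9e-08). NATA1 was listed at 0 in every combined library.

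Of the 2100 genes higher in h2a.z than in Col, 1384 (65.9%) were lower again in the combined line than in h2a.z and 39 were higher still. Of the 2100, 515 were still called higher than Col. Their median log2 fold change against Col was 1.08 in h2a.z and 0.21 in the combined line. Of the 909 lower genes, 303 (33.3%) were higher again and 69 lower still, with medians of -0.92 and -0.56. Because both contrasts share the h2a.z libraries, genes were also chosen on 2 libraries of each genotype and measured on the remaining ones, over 9 splits. The median was then 1.07 to 1.43 in the h2a.z library left out and 0.12 to 0.35 in the combined line. At least 87.7% of the genes lay lower there. For the lower set the median in h2a.z was 1.61 to 2.04 times that in the combined line. The count was 877 without h2a.z 1, 739 without h2a.z 2 and 728 without h2a.z 3. HTA9 stood at 32.1 TPM in h2a.z and 87.2 in the combined line. Lowered H3.3 and this change in HTA9 therefore cannot be told apart as the source of the return, and the splits do not separate them.

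**Figure D5:**
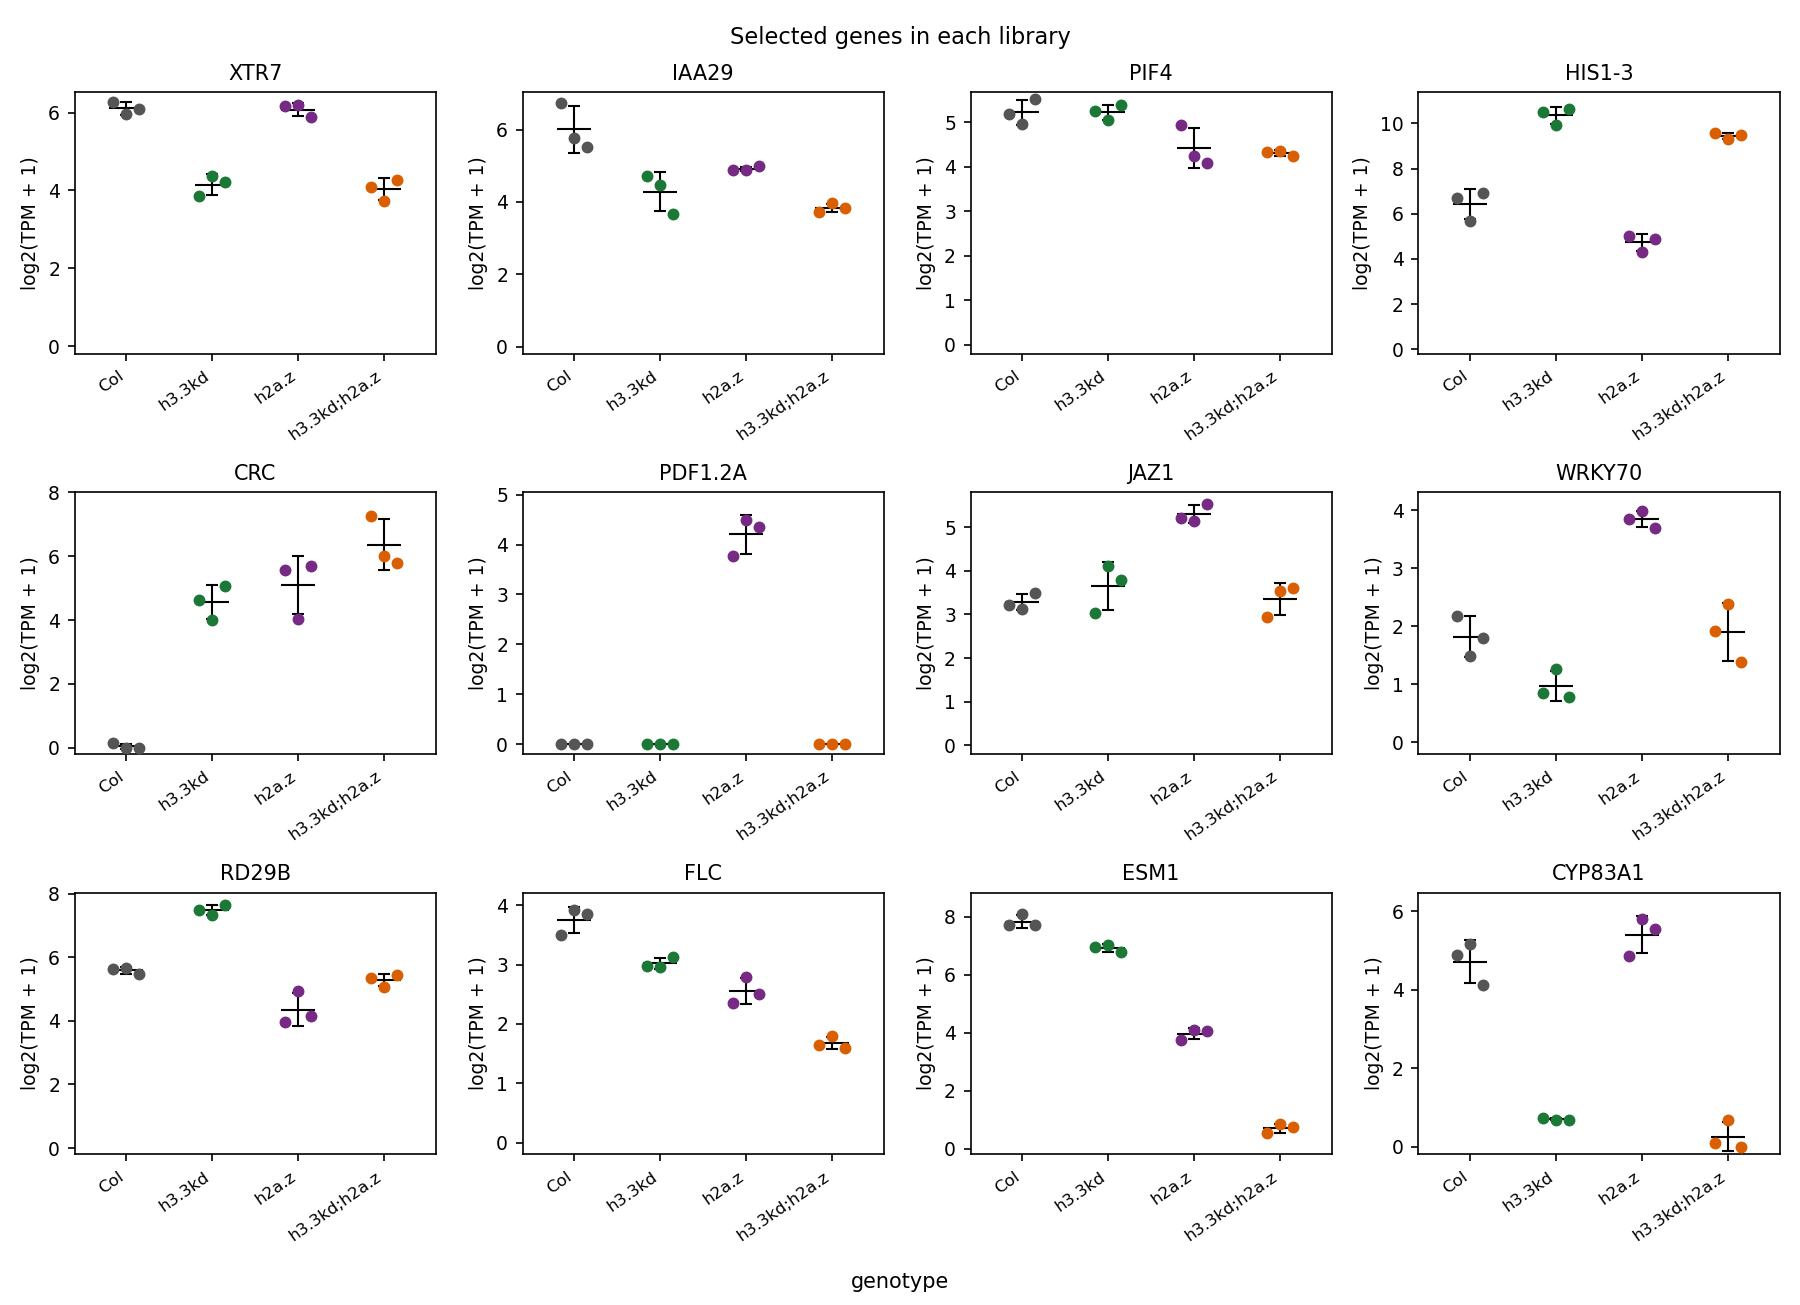
Transcript level of 12 genes as log2(TPM + 1), 1 point per library with the mean and SD of 3 libraries per genotype. XTR7 and IAA29 are low in h3.3kd and the combined line, CRC is near 0 in Col alone, and PDF1.2A, JAZ1 and WRKY70 are highest in h2a.z, at 17.9, 38.7 and 13.4 TPM.

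Against h2a.z, 1065 genes were higher and 3851 lower in the combined line (21.7% higher), with a median log2 fold change over all genes of -0.15. Leaving out h2a.z 2 gave 675 higher and 2563 lower, and leaving out combined 1, 2 or 3 gave 620, 692 or 673 higher. Median-ratio rescaling moved that median to -0.02 and gave 1883 higher and 3053 lower (38.1% higher). Quantile normalization moved it to 0.06 with 50.4% higher. The other 11 lists did not pass (adjusted p 0.18 to 0.40). Test, mean and median differed in sign for other H3 and H2A genes, thermomorphogenesis regulators, clock, ABA, and DNA damage response.

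The combined line against h3.3kd asks what the h2a.z change adds where H3.3 is low. RD29B fell from 179 ± 20.4 to 38.3 ± 5.26 TPM (n = 3, log2 fold change -2.20 ± 0.21, adjusted p = 1.6e-05) and P5CS1 from 90.3 ± 10.2 to 34.6 ± 2.05 (-1.35 ± 0.17, adjusted p = 2.2e-04). FLC fell from 7.12 ± 0.506 to 2.21 ± 0.237 TPM (-1.34 ± 0.19, adjusted p = 8.3e-04), and EXPA8 (AT2G40610), an expansin of the growth list, rose from 102 to 227 (1.15 ± 0.14, adjusted p = 1.4e-04). PIF4 was lower (-0.92 ± 0.21, adjusted p = 0.02), a call that ended at 0.086 without h3.3kd 3, 0.067 without h3.3kd;h2a.z 1, 0.066 without h3.3kd;h2a.z 2 and 0.084 without h3.3kd;h2a.z 3, with 1.3e-04 to 0.086 over all settings. YUC8 (-0.19 ± 0.21, adjusted p = 0.75), IAA19 (-0.46 ± 0.38, adjusted p = 0.63), IAA29 (-0.45 ± 0.29, adjusted p = 0.50) and HSP70-4 (0.33 ± 0.14, adjusted p = 0.25) did not pass.

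ABA, drought and cold genes had 4 of 17 lower and 0 higher (13 and 0 adjusted over the list alone). The list test gave adjusted p = 1.0e-12, and adjusted p = 0.13 with an estimated correlation, LTI30 among them (-1.60 ± 0.17, adjusted p = 8.0e-05). Seed and embryo markers had 3 of 7 higher and 0 lower (3 and 1 adjusted over the list alone). As a list they had adjusted p = 0.016, and adjusted p = 0.13 with an estimated correlation. CRA1 rose from 24.4 ± 12.5 to 159 ± 68.5 TPM (2.68 ± 0.48, adjusted p = 0.0048). Heat shock genes were higher as a list (adjusted p = 0.027, and adjusted p = 0.32 with an estimated correlation), with 2 called higher and 1 lower (3 and 1 adjusted over the list alone). HSP18.2 (AT5G59720) rose from 0.174 ± 0.301 to 6.59 ± 3.24 TPM (2.64 ± 0.31, adjusted p = 1.5e-04) and DREB2A fell (-1.06 ± 0.17, adjusted p = 0.002). Salicylic acid defence was higher (adjusted p = 0.027, and adjusted p = 0.33 with an estimated correlation), with 1 member called (3 adjusted over the list alone). Jasmonate and ethylene defence was lower (adjusted p = 0.016, and adjusted p = 0.32 with an estimated correlation), with 1 member called (1 adjusted over the list alone). Flowering time was lower too (adjusted p = 0.027, and adjusted p = 0.32 with an estimated correlation), with 1 called (4 adjusted over the list alone). Root markers were lower (adjusted p = 0.037, and adjusted p = 0.68 with an estimated correlation), with 2 of 16 called (3 adjusted over the list alone), a list call that ended at 0.057 after median-ratio rescaling. The targeted genes had 3 lower, the H2A.Z genes, as many adjusted over the list alone (adjusted p = 7.4e-07, and adjusted p = 0.13 with an estimated correlation).

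Among genes with a symbol, and leaving out the H2A.Z genes, the largest changes were ABCA9, LCR67 and PGAZAT upward. Their values were 3.93 ± 0.19 (adjusted p = 1.9e-08), 3.85 ± 0.43 (adjusted p = 8.6e-05) and 3.16 ± 0.30 (adjusted p = 1.6e-05), and LCR67 (AT1G75830) is a defensin. Downward, the largest in the same set were ESM1 (-6.20 ± 0.16, adjusted p = 1.1e-11), JAL33 (-5.72 ± 0.22, adjusted p = 1.7e-09), SEH (-4.02 ± 0.23, adjusted p = 1.4e-07) and GSTU8 (-2.96 ± 0.27, adjusted p = 1.4e-05). The jasmonate synthesis gene AOC2 (AT3G25770) fell as well (-2.90 ± 0.25, adjusted p = 8.1e-06). MYBL2 (AT1G71030), a repressor of anthocyanin genes, rose from 5.81 ± 0.166 to 13.1 ± 0.897 TPM (1.05 ± 0.18, adjusted p = 0.0037).

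In this comparison 484 genes were higher and 364 lower (57.1% higher). The direction turned without h3.3kd 1, with 429 higher and 484 lower (47.0% higher, median log2 fold change over all genes -0.06). Leaving out h3.3kd 2 gave 1111 higher and h3.3kd 3 gave 211 lower. The block for Col and h3.3kd gave 796 and 618, and a model of the compared genotypes alone 208 and 172. Leaving out combined 1, 2 or 3 gave 277, 235 or 267 higher and 214, 184 or 200 lower. Without Col 1 and h3.3kd 2 together 71.0% were higher. The other 11 lists did not pass (adjusted p 0.083 to 0.94), though other H3 and H2A genes did with that block (adjusted p = 0.047), with median below 0 and mean and test above it for flavonoid and anthocyanin genes.

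The interaction asks whether lowered H3.3 acts differently in plants without normal H2A.Z, where HTA9 transcript was lowered and not absent. For 369 genes the combined effect was below the sum of both single effects and for 127 above it, and with the block for Col and h3.3kd 611 were below and 229 above. Below the sum there were 177 at a pseudocount of 0.1 and 242 with a filter at 5 TPM. Among genes with a symbol, PGAZAT was farthest above (log2 difference 5.14 ± 0.42, adjusted p = 1.4e-05). It stood at 12.5 ± 6.03 TPM in Col, 7.97 ± 0.727 in h3.3kd, 2.30 ± 0.910 in h2a.z and 81.0 ± 19.4 in the combined line (n = 3). Of the genes with a symbol, RPP5 (3.68 ± 0.31, adjusted p = 1.6e-05) and TGG2 (AT5G25980), a myrosinase that splits glucosinolates (3.19 ± 0.34, adjusted p = 1.2e-04), followed. Below the sum were PRX52 (AT5G05340), a peroxidase, at 14.1 ± 8.31 TPM in h2a.z and 1.19 ± 0.785 in the combined line (-4.03 ± 0.51, adjusted p = 5.7e-04), and TAT3 (AT2G24850), an aminotransferase induced by jasmonate. TAT3 was listed at 0 in Col and stood at 12.2 ± 9.38 TPM in h2a.z and 0.0627 ± 0.109 in the combined line.

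Jasmonate and ethylene defence had 6 of 12 genes below the sum and 0 above (10 and 0 adjusted over the list alone). For this list camera gave adjusted p = 8.4e-13, and adjusted p = 0.015 with an estimated correlation. JAZ1 (-2.31 ± 0.36, adjusted p = 0.0031) and ORA59 (-3.12 ± 0.49, adjusted p = 0.0029) were below. At 0.828 TPM in Col, ORA59 could show little fall in h3.3kd. ABA, drought and cold had 3 of 17 below and 0 above (6 and 0 adjusted over the list alone). List-wide, camera gave adjusted p = 2.3e-05, and adjusted p = 0.34 with an estimated correlation. Salicylic acid defence had 2 below and 1 above of 16 (8 and 1 adjusted over the list alone). Taken as a list, these had adjusted p = 7.2e-04, and adjusted p = 0.26 with an estimated correlation. Phosphate starvation had 2 below and 0 above of 14 (4 and 0 adjusted over the list alone). Camera gave the list adjusted p = 7.2e-04, and adjusted p = 0.26 with an estimated correlation. Photosynthesis was above (adjusted p = 8.2e-04, and adjusted p = 0.65 with an estimated correlation), with 1 gene called (3 adjusted over the list alone). So were the targeted genes (median 0.56, adjusted p = 7.2e-04, and adjusted p = 0.26 with an estimated correlation). Of these only HTA9 was called (1.71 ± 0.31, adjusted p = 0.0073). HTA8 was near 0 in h2a.z and in the combined line, so it could show no further fall there. No growth gene passed (0 above, 0 below of 23 by limma, the same adjusted over the list alone).

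The count above the sum was 208 without h3.3kd 2, 69 without h2a.z 2, 78 without h2a.z 3, 72 without combined 1 and 81 without combined 3. Below the sum it was 238 without Col 2 or h3.3kd 3, 174, 139 or 131 without h2a.z 1, 2 or 3, and 215 or 240 without combined 1 or 3. The other 13 lists did not pass (adjusted p 0.21 to 0.86). Seed and embryo markers had a median of 0.11 with mean (-0.50) and test below 0, with such differences also in histone variant machinery and DNA damage response.

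Whether both single lines change the same genes was asked of 19937 genes against the shared Col libraries. There were 197 genes higher in both and 194 lower in both, against 114 and 108 for independent lists. The mean of same-way calls in simulations with no effect was 0. The former value leaves out the shared Col libraries and the latter the effects. Part or all of any excess may come from the Col libraries, which were not split between both comparisons here. Opposite ways went 403 genes, 65 higher in h3.3kd and lower in h2a.z and 338 the reverse, against 49.2 and 249.7 for independent lists. The 391 changed the same way became 698 with the block for Col and h3.3kd, 227 without Col 1, 235 without h2a.z 2 and 260 without h2a.z 3. Across genes, which are not independent replicates, the log2 fold changes had r = 0.08 (Spearman 0.08), against 0.50 (0.47 to 0.52) simulated with no effect and the same Col libraries. Without Col 1, 2 or 3 the observed r was 0.03, 0.15 or 0.15. Real effects add spread that the simulations lack, which dilutes r, so the observed and simulated r cannot be compared directly. The covariance was 0.0260, and 0.0331 in those simulations. It was thus not above the simulated value and shows no agreement beyond the shared Col libraries.

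Across all comparisons 7 lists passed in none. Against Col, the counts of higher and lower members in h3.3kd, in h2a.z and in the combined line were 1 and 2, 0 and 1, and 0 and 3 for 14 other H3 and H2A genes. For 15 genes of the variant machinery they were 1 and 0, 0 and 1, and 0 and 0. For 19 thermomorphogenesis regulators they were 1 and 0, 0 and 2, and 0 and 1. For 9 clock genes they were 1 and 2, 0 and 0, and 1 and 2. Flavonoid and anthocyanin genes (10 tested) had 0 and 2, 1 and 1, and 0 and 2. DNA damage response genes (9) had 1 and 0, 0 and 0, and 1 and 0. Floral organ and meristem markers (4) had 0 and 1, 2 and 0, and 0 and 0. Adjusted over the list alone the counts were the same, but for 2 other H3 and H2A genes and 0 regulators higher and 4 flavonoid genes lower in h3.3kd, and 0 machinery genes lower in h2a.z (limma).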

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

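The regrouping of deviations from the additive fit, the test of levels against scaling, the limit for reading the planned fit without h3.3kd 1, the matched genes beside the search for copies, the test of chromosome segments, the test of seed as 1 source with its condition on spread, and the fit without Col 1 and h3.3kd 2 were chosen only after the results they measure were seen. For the other tests of a pattern the outcome looked for was set down after the pattern was seen and before the test was run. Fewer reads as an explanation were not seen for h3.3kd, with an estimated mean of 15.9 M reads against 15.3 M in Col. That gap lies within the SD of 1.09 M in Col. Fewer reads stay open for the combined line, at 14.7 M. Regression to the mean was argued against for the genes higher in h2a.z, whose median there was at least 4.13 times that in the combined line in libraries not used to choose the genes. For the genes lower in h2a.z the ratio was 1.61 to 2.04, in 9 splits that share libraries, where regression alone would give 1, so it was argued against there as well. Neither is weighed here, a choice made after those values were seen.

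The effect of lowered H3.3 differed between plants with and without normal H2A.Z for 127 genes above the sum of both effects and 369 below it. With the block for Col and h3.3kd these were 229 and 611, and below it were 177 at a pseudocount of 0.1 and 242 at 5 TPM. HTA9 stood at 32.1 TPM in h2a.z and 87.2 in the combined line. The H3.3 effect without normal H2A.Z therefore comes together with a change in HTA9. Of 100 regroupings of the deviations from the additive fit, 1 gave as many calls, the real one (496), and the highest other gave 7, so chance is argued against. Regrouping whole libraries was planned and gave 2 of 100 (highest other 706), but it puts both single effects into the spread and decides nothing. For the comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real split was 1 of 10 each time, with 3450 calls in h3.3kd (highest other 5), 3009 in h2a.z (1), 3738 in the combined line against Col (0), 4916 against h2a.z (0) and 848 against h3.3kd (0). Of the 4 splits of Col and h3.3kd libraries that part all 3 same-numbered pairs, the highest besides the real one gave 0 calls (limma).

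Of 133 named genes, 30 passed in the interaction by limma, at an adjusted p of at most 0.04. Differences are on log2(TPM + 1), where NATA1, PDF1.2A and TAT3 were listed at 0 in Col and could not fall in h3.3kd. ORA59, EARLI1, DIN11 and PRX52 stood under 1 TPM in Col, PRX52 at 0.0358. PR5 was listed at 0 in every h3.3kd library. MES18 stood at 4.15 TPM in Col and 0.126 in h3.3kd, and BCAT4 at 1.88 and 0.351. For these genes the floor limits the fall that h3.3kd can show. Their differences therefore do not show a larger H3.3 effect without normal H2A.Z. Below the sum were jasmonate and defence genes, PDF1.2A (log2 difference -4.21), ORA59 (-3.12), AOC1 (-2.46), JAZ1 (-2.31), AOC2 (-1.71), NATA1 (-4.85), TAT3 (-3.53) and PR5 (-1.88). So were EARLI1 (-3.39), PRX52 (-4.03), DIN11 (-2.70), MES18 (-2.77), BCAT4 (-3.27), ESM1 (-2.34) and JAL33 (-1.56). IRT1 (-1.91), the cold genes COR15B (-1.50) and LTI30 (-1.26), and the phosphate genes GDPD1 (-1.23) and PAP17 (-1.18) belong here too. On the log2 scale the seed genes CRC (-3.26) and CRA1 (-2.82) were below the sum as well. Yet CRC stood at 0.0321 TPM in Col, 23.7 in h3.3kd, 37.5 in h2a.z and 90.6 in the combined line. CRA1 stood at 0.525, 24.4, 77.7 and 159. Both rise from near 0 in Col and were highest in the combined line, so their differences do not show that the effects cancel. Above the sum were PGAZAT (5.14), RPP5 (3.68), TGG2 (3.19), GH9B15 (3.01), PAI3 (2.49), SNC1 (1.90), HTA9 (1.71) and RBCS1B (0.81).

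As lists, jasmonate and ethylene defence differed by H2A.Z at an adjusted p of 8.4e-13, ABA, drought and cold at 2.3e-05, photosynthesis at 8.2e-04, and the targeted histone genes, phosphate starvation and salicylic acid defence at 7.2e-04 each. With an estimated correlation only jasmonate and ethylene defence kept an adjusted p under 0.05, at 0.015. Its members PDF1.2A and ORA59 are among the genes whose fall in h3.3kd is limited by the floor.

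More genes were lower than higher in h3.3kd and in the combined line (32.9% higher) than in Col. In h3.3kd the libraries Col 1 and h3.3kd 2 do not account for it (26.2% higher without both), while h3.3kd 1 may carry part of it (40.2% without it), and there library and genotype cannot be told apart. The split depends on scaling, as median-ratio and quantile scaling, which centre the libraries, gave 48.0% and 52.8% higher in h3.3kd and 45.9% and 50.2% in the combined line. A few abundant transcripts in the TPM total are not the whole cause, since they would move all levels alike, and the lowest sixth of levels differed from the highest by -0.35 in h3.3kd (-0.41 to -0.25 with 1 library left out) and -0.27 in the combined line (-0.33 to -0.19). A smaller share of root may add to it, as 15 of 16 root markers were below 0. Their spread was 1.46 times their median standard error (0.42 against 0.29), under the limit set before the test. They ran from -1.53 (IRT1) to 0.23 (SCR), so an equal fall is not shown. Their mean log2(TPM + 1) was 2.55, 3.16 and 3.42 in h3.3kd 1, 2 and 3, against 3.52 to 3.90 in Col. A biological loss of transcripts with lowered H3.3 stays open and was not tested, since TPM values give no absolute amounts.

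For the 34 transcripts near 0 in h2a.z, reads shared with a copy beside the gene account for few, since 2.94% (1 gene) had a same-product gene within 2 places that gained at least 0.5 of the lost TPM. Copies elsewhere and a true loss cannot be told apart, since 53.3% of 30 searched genes had such a gene anywhere, and so did 50.5% of matched genes outside the set. Chromosome segments of another strain, left in the h2a.z line by crossing, could give such losses. Successive genes of the set on a chromosome, more than 10 places apart, shared loss or recovery in the combined line more often than shuffled ones. This held for 18 of 24 pairs against a mean of 11.6 (one-sided permutation p = 0.00695 over 100000 resamples). Genes within 10 places of each other were counted once, by the first. Of those left out, AT1G29100 differed in state from AT1G29090. AT3G21380, AT4G16957, AT4G19510 and AT5G51630 shared the state of the first gene of their run. A direct effect of lowered H2A.Z on these genes stays open, and RPP5, PAI3, JAL33 and, beside RPP5, SNC1 should be read with these in mind. ESM1 fell from 228 TPM in Col to 14.7 in h2a.z, just short of the 16-fold limit. It was thus not in the set, and the same caution holds for it. Only the set of h2a.z is weighed here, while 38 transcripts were near 0 in the combined line, 9 of them in both.

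The seed genes CRC, CRA1 and PAP85 were higher in the 3 mutant genotypes, but the seed list did not pass in h2a.z (adjusted p = 0.097), where 7 of 10 LEA family genes were lower. In the combined line the TPM total does not account for it. Median-ratio rescaling moved the median of all genes there only from -0.10 to -0.01, against a seed list median of 2.51. The 5 seed markers still called higher after it could thus hardly have lost their calls. Leftover or ungerminated seed may be the source, and it would keep the transcripts in 1 ratio. The log2 ratio of SESA5 to CRA1 differed by 2.17 between h3.3kd and h2a.z, less than the SD of 3.34 within h3.3kd. In that genotype it was -4.30, 1.43 and 1.55, so this pair did not keep 1 ratio there. The low value rests on 1 library, and 1 pair does not decide for the other seed genes. Seed and expression in the seedling therefore cannot be told apart for the seed genes as a set. Expression of seed genes in seedlings of altered chromatin stays open as the biological explanation.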

How the results depend on the processing

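Leaving out Col 1 and h3.3kd 2 together and a block for Col and h3.3kd alone were chosen after the data were seen. The other alternatives were planned. Of 7011 alternative values for 283 results on named genes, 6503 kept their direction and side of the threshold, 503 kept their direction but no longer passed, 5 newly passed and 0 turned round. Of those no longer passing, 279 came from leaving out 1 library, 77 from a 2-fold minimum, 47 from models of only the genotypes compared, 30 from quantile normalization and 15 from median-ratio rescaling. With the replicate number as a block 7 of 283 no longer passed, no count moved by over 1.5 times, and 0 of 114 list tests changed. Of 12 libraries, 9 correlated best with their own number, and 6 of 18 same-numbered pairs had r over 0.1 (-0.18 to 0.31). With a block for Col and h3.3kd alone HTA11 in the combined line against h2a.z (adjusted p = 0.043) and the list of other H3 and H2A genes against h3.3kd (0.047) newly passed, and it changed no other call on a named gene or list. Of 38 list tests that passed of 114, 4 passed with an estimated correlation and 1 ended with median-ratio rescaling. A 2-fold minimum does not apply to a correlation, nor a model of only the compared genotypes to the interaction. Depth limits calls near 1 TPM.

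The cause of the shifts was not tested, except that a 2-fold minimum calls fewer genes by construction. The block for Col and h3.3kd was chosen because their libraries deviated together in these data. It takes that out of the spread, so its higher counts are no independent check. Counts are higher then lower. Against Col, h3.3kd (1079 and 2371) gave 1680 higher with the block for Col and h3.3kd, 1733 higher with median-ratio rescaling, 1649 and 1473 with quantile normalization, 2224 and 4593 with array weights, 287 and 784 with only the compared genotypes, and 293 and 1056 at 2-fold. The h2a.z counts (2100 and 909) became 1578 lower with quantile normalization, 3584 and 1932 with array weights and 1186 and 401 at 2-fold. The combined line against Col (1230 and 2508) gave 1861 higher with that block, 2162 and 4129 with array weights, and 451 and 1269 at 2-fold. Against h2a.z (1065 and 3851) it gave 1883 higher with median-ratio rescaling, 2512 and 2473 with quantile normalization, 2621 and 6552 with array weights, 2125 higher with only the compared genotypes, 285 and 2049 at 2-fold, and 1941 higher without Col 1 and h3.3kd 2. Against h3.3kd (484 and 364) it gave 796 and 618 with that block, 2974 and 2497 with array weights, 208 and 172 with only the compared genotypes, 285 and 215 at 2-fold, and 1589 and 648 without Col 1 and h3.3kd 2. The interaction (127 above, 369 below) gave 229 and 611 with that block, 907 and 1894 with array weights, 310 and 556 without Col 1 and h3.3kd 2, and below it 177 at a pseudocount of 0.1 and 242 at 5 TPM. Genes changed the same way (391) were 698, 980, 179 and 135 with that block, array weights, compared genotypes and 2-fold, and lower-again genes (1384) were 2542 with array weights, 753 at 2-fold and 911 at 5 TPM. The array weights did not reach their convergence tolerance.

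With 1 library left out, h3.3kd gave 711 (without h3.3kd 3) to 1337 higher and 1427 (Col 1) to 3395 lower. For h2a.z it was 1252 (h2a.z 3) to 2664 higher and 514 (h2a.z 2) to 1273 lower. The combined line gave 757 (combined 2) to 1717 and 1599 (combined 2) to 3305 against Col, 620 (combined 1) to 1527 and 2563 (h2a.z 2) to 4749 against h2a.z, and 235 (combined 2) to 1111 and 184 (combined 2) to 484 against h3.3kd. The interaction gave 69 (h2a.z 2) to 208 above and 131 (h2a.z 3) to 551 below. Same-way genes were 227 (Col 1) to 505, lower-again genes 728 (h2a.z 3) to 1748, and the correlation 0.03 (Col 1) to 0.15.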

Other observations

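The list of glucosinolate genes was written after 4 of them had been noticed, and the families were taken from product names after the data were seen.

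Families of genes with the same product name moved in ways the fixed lists do not cover. In h2a.z against Col, 55 of 139 cytochrome P450 genes were higher and 7 lower (median log2 fold change 0.49, camera adjusted p = 1.0e-05 over 252 families). There, 12 of 19 berberine enzyme genes were higher (1.0e-05) and 16 of 26 cysteine-rich receptor kinases (0.89, 3.1e-05). Of 10 LEA family genes, 7 were lower (-1.54, 3.8e-05). In the combined line against h2a.z, 39 of 55 peroxidase genes were lower (-1.37, 6.8e-10), as were 71 of the 139 P450 genes (-0.66, 7.4e-04) and 24 of 43 WRKY transcription factors (-0.79, 0.0020). There 8 of 16 root markers were lower as well (-0.77). None of the families passed with an estimated correlation (adjusted p of 0.35 or more).

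In h3.3kd against Col, 16 of 27 arabinogalactan protein genes, which belong to the cell surface, were lower and 1 higher (-0.99, 4.9e-04), and so were 19 of 46 lipid transfer and albumin genes (-0.81, 1.3e-05). Of 13 genes named root hair specific, 10 were lower in the combined line than in Col (-0.96, 0.0042). Root markers were lower too, 5 of 16 in h3.3kd (-0.76) and 10 of 16 in the combined line (-0.93), so the root share is not set aside for the families lower in these comparisons.

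A hypothesis is that aliphatic glucosinolate synthesis as a whole is lower with lowered H3.3, beyond CYP83A1, MAM1, BCAT4 and IPMI2. Of 18 tested genes of the pathway, 13 were lower in h3.3kd and 0 higher (limma, median -1.16), and of the 14 others 9 were lower (camera p = 6.11e-06, and p = 0.055 with an estimated correlation), which is consistent with a lower pathway at the preset correlation. MYB28, its main regulator, fell from 27.3 ± 6.51 to 3.22 ± 0.676 TPM (log2 fold change -2.73 ± 0.20, adjusted p = 2.4e-06, n = 3). In h2a.z 9 of the 18 were higher and 2 lower than in Col, and in the combined line 15 were lower than in h2a.z. Root markers were lower as well, 5 of 16 in h3.3kd against Col and 8 of 16 in the combined line against h2a.z. The root share is therefore not set aside for this pathway.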
